A study of Saccharomyces cerevisiae with 593 samples.

How the data were processed

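The series holds 593 hybridisations of Saccharomyces cerevisiae RNA to 2-colour arrays, each of which compared the RNA of a treated, depleted or mutant culture with that of a reference culture. Per the labels, total RNA was extracted with acid phenol, aminoallyl-dUTP was incorporated during cDNA synthesis, and the products were coupled to Cy3 or Cy5. Titles, source names and characteristics gave each array's strain, treatment, time, control, replicate and batch. Treatments were 1 M KCl, 0.5 M NaCl, 300 mM LiCl, 1 M sorbitol, 1 or 10 mM dithiothreitol (DTT), 50 mM 3-aminotriazole (3-AT), 20 uM of the casein kinase 2 inhibitor TBB, 200 ng/mL rapamycin, 5 ug/mL sulfometuron methyl (SMM), 1 mg/mL wortmannin, heat shock at 42 degrees Celsius, and media without amino acids, histidine, nitrogen, glucose, inositol or phosphate. Samples were taken after 5, 10, 15, 20 or 40 min, and after 60 min in KCl; 3-AT with TBB, and deletion strains before treatment, were also sampled at 0 min. For single treatments of the wild type, controls were untreated cells of the same time, except for 3-AT, rapamycin, DTT, wortmannin and TBB, which were compared with cells taken before treatment. A second heat shock course was set over untreated cells of time 0, and KCl and LiCl at 20 min were also set over cells before treatment. Deletion strains were compared with untreated cells of the same time in KCl, in rapamycin and in histidine depletion, and with cells before treatment in 3-AT and SMM; rrp6 and ckb deletions were also set over the wild type. Combined treatments were compared with untreated cells of the same time, cells before treatment, or cells given 1 of the treatments. The labels do not say whether replicates are independent cultures. Where the genotype entry of the ckb2 arrays names ckb1, the strain of the title was used.

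The deposited values were read as log2 ratios of the labels' channel 1 over channel 2 for each spot, centred near 0, and the labels do not state the base of the logarithm, the centring or any normalization within an array. They ran from -17.7 to 10.8; base 2 was assumed, on which the lowest values are already beyond the usual ratio of 2 scanner readings, and they would lie further beyond it on a larger base. Medians of the arrays lay between -0.0391 and 0.0477, and no further scaling was applied. The dyes of the labels were checked with the dye effect, which followed them in 282 of 282 dye-swapped pairs (lowest correlation over oligos 0.230, median 0.671). This check cannot see an exchange of treated and control RNA, nor a sign shared by all arrays. The direction of the ratio was checked with RRP6 in the strain that lacks it, which covers the arrays of that strain over the wild type only. For 11 array identifiers the treated RNA is labelled as channel 2, and the sign was changed to give treated over control. Of these, the 7 identifiers of batch C ran against their own replicates after this change, and their direction could not be settled; they were used as labelled, with alternatives in which they were turned or left out. The files hold no spot intensities, so signal over background could not be examined.

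Each array holds 9216 spots, and the layout repeats 1536 oligos in 6 copies. Copies of an oligo had a median standard deviation of 0.141 on an array, against 0.394 for random sets of 6 spots. A gene symbol was given for 8742 spots, all found in the reference gene table, and 474 had none, which leaves 1457 named and 79 unnamed oligos. Of 982 genes, 747 have 1 oligo, 4 have 2, 222 have 3 and 9 have 4. The annotation does not say which oligo reads an exon, an intron or a junction, so the planned index of intron against exon could not be formed, and the oligo was tested in place of the gene. Oligos of 1 gene are numbered in the order of their position on the array. In place of the index, the difference of an oligo from the mean of its gene's other oligos was tested for 702 oligos of 231 genes, a choice made after the data were seen, and it is reported for the 4 comparisons with over 350 changed oligos. No genome build is stated, so no coordinates are given. The deleted genes CKB1, CKB2, HIS3, EDC2, CKA1 and CKA2 are not analysed here.

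The 6 copies of an oligo were averaged on each array, and the 2 dye orientations of an identifier were averaged into 1 replicate value; 282 of 311 identifiers have both orientations, and 28 arrays come from the batch run in 1 orientation only. Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, matrixStats 1.5.0) in 1 fit with a mean for each of the 79 groups with 2 or more replicates, 195 replicate values and 116 residual degrees of freedom. Group means at 20 min were tested against 0 in 14 comparisons and against each other in 3, two-sided, with p adjusted by Benjamini and Hochberg over the 1457 named oligos and a threshold of 0.05. Counts at an unadjusted p under 0.05 are also given. With no change, a share of about 0.05 of the tested oligos would fall there. A count near or below that share is no sign of a change. The 116 groups with 1 replicate, the other times and the combined treatments are given as values without a test. Errors are standard deviations between replicate values. The p of limma rests on an oligo's spread over all groups of the fit, so it can be small beside a large standard deviation, or large beside a small one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and figures.

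Fixed gene lists were tested with limma's camera, which compares a list's oligos with all others, at a preset correlation between genes of 0.01 and again with an estimated correlation; 14 lists in 17 comparisons gave 238 tests, adjusted together. Missing replicate values (1117 of 284115) were filled with the group mean for camera only. The lists, written from general knowledge, were (measured of listed genes) amino acid biosynthesis (6 of 73), general stress response (8 of 51), glucose derepressed genes (3 of 37), mating pathway (7 of 20), heat shock chaperones (8 of 31), inositol and phospholipid synthesis (4 of 23), meiosis and sporulation (16 of 46), nitrogen catabolite repression (4 of 34), nuclear exosome and RNA decay (22 of 31), osmotic stress and glycerol (5 of 24), splicing factors (80 of 85), ribosome biogenesis (40 of 108), unfolded protein response (3 of 32) and ribosomal proteins (126 of 126, by symbol). The amino acid list was measured through GCN4, HIS2, HIS4, HIS5, LYS14 and HMT1, which is an arginine methyltransferase gene. The ribosomal protein symbols took in RPP1, an RNase P gene. Some genes are in more than 1 list. HSP104, SSA3 and SSA4 are chaperone and general stress members, and ALD3 is a general stress and osmotic member. RRP4 is in the ribosome biogenesis and exosome lists. Results of these lists are therefore not separate from each other. Phosphate starvation (2 of 21) was too small to test, and casein kinase 2 subunits (0 of 4) and mitochondrially encoded genes (0 of 8) are not analysed here.

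The procedure was tested on simulated data in 20 runs each, made from residual columns drawn from all groups of the fit. These keep the correlation between oligos but not differences in spread between groups, batches or controls that groups share. The rates below therefore hold for groups of equal spread. With 200 changed oligos, log2 changes of 0.5, 1 and 2 were recovered in 81.9%, 99.2% and 100% of cases with 4 replicates (KCl), 70.1%, 98.0% and 100% with 3 (3-AT) and 54.4%, 95.7% and 99.9% with 2 (heat shock). False calls made up 6.04%, 17.0% and 5.52% of the called oligos. With no change, 16, 13 and 15 of the 20 runs called no oligo, and the highest counts were 30, 226 and 14. With the preset correlation, camera called the ribosome biogenesis list, whose genes vary together, in 16, 12 and 11 of 20 runs without any shift. With an estimated correlation it called the list in 2, 1 and 0. List calls in these runs were at an unadjusted p under 0.05, while those in the results are adjusted. When the list was shifted by -0.5, the estimated correlation called it in 3, 1 and 0 of 20 runs. The preset correlation therefore calls lists of genes that vary together too often and the estimated one has little power, so both are printed and the counts of oligos per list come first.

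The comparisons, tests, lists, the rule for naming genes and 11 of the alternatives were fixed before the data were examined. For KCl, LiCl, 3-AT, both histidine depletions, rapamycin and heat shock the rule named, among oligos past the threshold with the same sign in every replicate, the 6 highest and 6 lowest means, the 5 highest and 5 lowest differences within genes, and the 2 members of each list with the largest absolute mean; for other comparisons it named 4 and 4 oligos and 3 and 3 differences. It also covered the deleted genes, HAC1 in DTT and, in groups with 1 replicate, the 3 highest and 3 lowest oligos with the same sign in both orientations. The text names part of these, and any gene outside the rule is given as one chosen after its values were seen. Alternatives fixed beforehand were the array median subtracted, the median of the copies, arrays with the treated RNA in Cy5 alone, the dye effect subtracted, a fit to the compared replicates alone, batch as a random block, the noisiest oligos left out, each replicate left out, a further heat shock course added, the estimated correlation, and intron against junction oligos, which could not be formed. Alternatives added later were the unsettled arrays turned or left out, the mean of all oligos of a gene, arrays with over 20% of spots missing left out, identifiers with both orientations alone, the oligos that moved together left out, and batch as a fixed term.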

Results

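The arrays compared RNA from Saccharomyces cerevisiae cultures under stress or nutrient depletion with RNA from reference cultures, on 2-colour arrays designed for the study of splicing. The collection holds 593 arrays of 311 array identifiers, and 282 identifiers were hybridised in both dye orientations. Each array carries 9216 spots, which hold 1536 oligos in 6 copies each. Of the oligos, 1457 carry a gene name and report on 982 genes; 231 genes have 3 or 4 oligos each. The wild type supplied 394 arrays as the treated or depleted strain. The remaining arrays came from strains that lack CKB1 and CKB2 together (50 arrays), RRP6 (34), HIS3 (32), HOG1 (16), CKB1 (12), CKB2 (12), EDC2 (8), CKA1 (2) or CKA2 (2), and from a HIS3 repaired strain (31). The identifiers fall into 195 groups of strain, treatment, time and control. Of these, 79 groups have 2 or more replicates and 116 have 1. Between 0.033% and 64.1% of the spots of an array were missing, with a median of 4.64%, and 26 arrays lacked over 20%. The number of arrays limits the precision: the median standard error of an oligo's mean log2 ratio at 20 min was 0.127 with 4 replicates and 0.180 with 2.

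Wild-type cells in 1 M KCl were compared with untreated cells of the same time to ask which transcripts change in osmotic and potassium stress. After 20 min, oligos for the serine tRNA gene SUP16 rose by 2.17 ± 1.43 log2 units (SD, n = 4; limma adjusted p = 2.97e-06), and those for YNCD0013C, another tRNA gene, by 1.23 ± 0.47. Not all tRNA oligos rose: that of SUP61, chosen after its values were seen, stood at -1.02 (limma adjusted p = 9.78e-07). The ribosomal protein gene RPL38 rose by 1.10 ± 0.02, and 1 oligo each of DTD1, a D-aminoacyl-tRNA deacylase, and QCR9, a subunit of the respiratory chain's cytochrome bc1 complex, by 1.19 ± 0.27 and 1.04 ± 0.12. RPP0, which encodes the ribosomal stalk protein P0, was the lowest at -2.10 ± 0.68 (limma adjusted p = 2.12e-16), followed by NMD2 oligo 3 at -1.45 ± 0.45, the zinc finger gene AZF1 at -1.33 ± 0.38, the fibrillarin gene NOP1 at -1.33 ± 0.38 and the elongation factor gene SPT5 at -1.24 ± 0.17. In all, 425 of 1457 oligos changed, 216 upward and 209 downward. Among ribosomal protein oligos 72 of 330 rose and 60 fell (82 and 64 adjusted over the list alone; limma's camera gave no net direction against the other oligos, adjusted p = 0.961). Splicing factors had 23 of 90 oligos up and 11 down (27 and 11 adjusted over the list alone; camera adjusted p = 0.0433, upward), a call lost with an adjusted p = 0.374 with an estimated correlation; the branch point binding protein gene MSL5 at -1.07 ± 0.36 and the tri-snRNP gene DIB1 at -0.98 ± 0.09 were the lowest members. Of the osmotic and glycerol list 1 of 5 oligos passed, for the glycerol channel gene FPS1 at -0.23 (limma adjusted p = 0.0336), and of the chaperones 1 of 8, for SSA1, both downward and named after the values were seen. GPD1, the glycerol synthesis dehydrogenase, stood at -0.42 ± 0.26 and the disaggregase gene HSP104 at 0.70 ± 0.28, and neither passed the test (limma adjusted p = 0.204 and 0.275). That test uses the spread over all groups, so it does not show that these genes were unchanged. HSP104 stood above 0 in batches A, G and H, at 0.99, 0.49 and 0.85. Without replicate 2 the count was 259, and the Hsp70 gene SSA1, at -0.70 ± 0.55 with all replicates, no longer passed (-0.48).

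Oligos of 1 gene often moved apart in KCl. The files do not say which oligo reads an intron, a junction or an exon, so whether splicing changed cannot be read from these differences. An oligo's difference from the mean of its gene's other oligos changed for 267 of 702 oligos (limma, 141 upward and 126 downward), in 142 of 231 genes. RPS22B oligo 1 lay 1.07 ± 0.38 above the other RPS22B oligos (SD, n = 4; own mean 0.71, others -0.36), and RPL42A oligo 1 lay 0.95 ± 0.11 above its own, whose mean was 0.01. RPL25 oligo 2 differed by -1.48 ± 0.33, with its own mean at -0.66 and the others at 0.82, and RPS10A oligo 2 by -1.07 ± 0.22. Ribosomal protein genes held such an oligo more often than other genes, 72 of 98 against 70 of 133 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00214 over 4 comparisons). Here and for the other treatments this test counts genes of the same arrays as independent, so its p does not measure the spread between replicates. A set of 25 oligos of unrelated genes, with a median of -0.83 in KCl, moved together over all replicate values. The set was picked by a correlation above 0.8 with NMD2 oligo 3 over these values. Their shared movement, also in KCl, is therefore in part a result of the choice of these oligos. Among them were NMD2 oligo 3, AZF1, MSL5, DIB1 and SUP61 but not RPP0, NOP1 or SPT5. NMD2 oligo 3 and QCR10 oligo 2, both among them, held the lowest differences within genes, at -1.54 and -1.51. The 21 other oligos of the same genes had a median of 0.13. Without replicate 2 the number of changed differences was 168, and with the noisiest oligos left out, 1093 being kept, it was 139.

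Lithium, given as 300 mM LiCl, raised chaperone, general stress and osmotic stress genes within 20 min and lowered ribosome biogenesis genes. The disaggregase gene HSP104 rose by 3.35 ± 0.81 (SD, n = 3; limma adjusted p = 1.38e-07), the inducible Hsp70 gene SSA4 by 3.11 ± 0.40, the aldehyde dehydrogenase gene ALD3 by 3.03 ± 1.01, the sodium and lithium pump gene ENA1 by 2.80 ± 0.43 and the salt tolerance regulator CIN5 by 2.29 ± 0.61. All 8 chaperone oligos rose, as did 8 of 10 general stress oligos and 4 of 5 osmotic oligos, and the numbers adjusted over the list alone were 8, 8 and 4. HSP104, SSA3 and SSA4 count in both of the first lists and ALD3 in both of the last, so these numbers overlap. Camera gave adjusted p = 1.26e-05, 7.53e-05 and 0.00036 for these lists, and adjusted p = 0.306, 0.306 and 0.135 with an estimated correlation. Ribosome biogenesis genes had 31 of 44 oligos down (31 adjusted over the list alone; camera adjusted p = 4.48e-13, and 0.266 with an estimated correlation). The lowest were NOG2 oligo 1 at -2.28 ± 1.04, a GTPase of the large subunit's assembly, and RRS1 at -2.04 ± 0.78. The other NOG2 oligos lay from -0.86 to -0.43. Ribosomal protein oligos fell in 107 of 330 cases and rose in 9 (107 and 9 adjusted over the list alone; camera adjusted p = 1.27e-10, and 0.374 with an estimated correlation), with RPL7B oligo 3 at -2.26 ± 0.55. RPL7B oligo 2 stood at -0.43. In all 493 of 1457 oligos changed, 251 upward and 242 downward. A limma fit to the LiCl replicates alone called 269.

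Differences between oligos of 1 gene were also common in LiCl, for 248 of 702 oligos in 117 genes (limma, 137 upward and 111 downward). RPS19B oligo 3 lay at -2.18 ± 0.95 (SD, n = 3; limma adjusted p = 1.90e-17) against the gene's other oligos, whose mean was 0.01, and RPS0B oligo 3 and RPL36B oligo 1 lay at -1.98 ± 0.80 and -1.89 ± 0.42. OM14 oligo 1, for a protein of the mitochondrial outer membrane, lay 1.99 ± 0.33 above its gene's others, with its own mean at 2.40. Ribosomal protein genes held a differing oligo in 72 of 98 cases and other genes in 45 of 133 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 5.80e-09). With the LiCl replicates fitted alone 0 of these differences passed in limma, against 292 at an unadjusted p under 0.05 in the full fit; without replicate 3 the number was 125, and without the noisiest oligos it was 98.

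Sodium, as 0.5 M NaCl, raised general and osmotic stress genes and lowered ribosome biogenesis genes. ALD3 rose by 2.65 ± 1.23 (SD, n = 2), HSP104 by 2.15 ± 0.39 (limma adjusted p = 0.0164), CIN5 by 2.08 ± 0.42 and ENA1 by 1.76 ± 0.11 (limma adjusted p = 2.11e-05). The rRNA methyltransferase gene SPB1 fell by 2.01 ± 0.56, and the assembly factor gene RRS1 and the nucleolin gene NSR1 stood at -1.45 ± 0.02 and -1.43 ± 0.52. General stress oligos rose in 6 of 10 cases, chaperones in 4 of 8 and osmotic oligos in 3 of 5, or 8, 5 and 5 adjusted over the list alone. Camera from limma gave these lists adjusted p = 1.21e-05, 0.000236 and 6.06e-05, and adjusted p = 0.247, 0.378 and 0.0840 with an estimated correlation. Of the ribosome biogenesis oligos 24 of 44 fell, and of the ribosomal protein oligos 62 of 330 fell and 2 rose (30, 64 and 3 adjusted over the list alone). Their camera adjusted p from limma were 4.42e-16 and 1.67e-11, and adjusted p = 0.150 and 0.352 with an estimated correlation. Limma called 226 of 1457 oligos, 106 upward and 120 downward. Without replicate 1 the count was 19 and without replicate 2 it was 58. HSP104 and RRS1 passed in neither case, at 2.43 and -1.46 without replicate 1 and at 1.87 and -1.44 without replicate 2, and ALD3 (1.78) and NSR1 (-1.06) were lost without replicate 1.

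The KCl and LiCl responses, to salts that differed in both ion and concentration, were compared directly at 20 min. The differences below therefore do not separate the ion from the dose or its osmotic strength. Later times were not tested, so a gene that responds later in KCl cannot be told apart here from a gene that does not respond. ENA1 differed by -2.93 between KCl and LiCl on the log2 scale (means -0.13 ± 0.07 with n = 4 and 2.80 ± 0.43 with n = 3; limma adjusted p = 1.24e-11). The chaperone gene SSA4 differed by -3.19 (-0.08 and 3.11; limma adjusted p = 1.35e-07), ALD3 by -3.02 and HSP104 by -2.65. RPL22B oligo 1 differed by 2.32 (0.24 and -2.07), NOG2 oligo 1 by 2.20 and RPC19, a subunit shared by RNA polymerases I and III, by 2.19 (0.54 and -1.65). Not all oligos of these genes fell as far in LiCl. RPL22B oligo 2 stood there at -0.46, and the other NOG2 oligos lay from -0.86 to -0.43. All 8 chaperone oligos and 4 of 5 osmotic oligos were lower in KCl, and 27 of 44 ribosome biogenesis oligos were higher (30 adjusted over the list alone); camera gave adjusted p = 1.42e-05, 0.000177 and 2.08e-10, and with an estimated correlation adjusted p = 0.306, 0.130 and 0.313. In all 441 of 1457 oligos differed, 213 higher and 228 lower in KCl. Batch H holds 1 KCl and 2 LiCl replicates, and there ENA1 differed by -2.77, HSP104 by -2.15, ALD3 by -2.26 and GPD1 by -1.75 (pooled -2.27). Fitted to these groups alone, limma called 470 oligos without a batch term and 0 with batch as a fixed term, against 588 at an unadjusted p under 0.05 in the full fit.

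Over time the wild type in KCl had GPD1 at -0.44 ± 0.09 after 5 min (SD, n = 3), -0.42 ± 0.26 after 20 min, 0.57 ± 0.34 after 40 min (n = 4) and 1.10 after 60 min (n = 1). ENA1 stood at 1.02 and HSP104 at 2.53 after 60 min. In LiCl, GPD1 was already at 1.92 ± 0.75 and ENA1 at 1.87 ± 0.71 after 5 min (n = 3), and ENA1 stood at 1.05 ± 0.14 after 40 min. In NaCl, GPD1 stood at 0.93 ± 0.75 after 5 min and 1.69 ± 0.20 after 40 min (n = 2), and ENA1 at 0.10 ± 0.14 and 2.11 ± 0.29. Sorbitol at 1 M, an osmotic stress without salt, was measured in 1 replicate: GPD1 stood at 1.32 after 20 min and 1.43 after 40 min, and ENA1 at -0.13 and 1.53. These times were described and not tested.

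Responses of the salts were also compared across the 1457 oligos, which are not independent replicates. LiCl and NaCl correlated with Pearson's r = 0.877 and Spearman's rho = 0.830 (covariance 0.194, against r = 0.354 and covariance 0.0138 simulated with a shared control and no effect; r = 0.843 between single replicates of other batches). Of the called oligos, 86 were higher and 115 lower in both, against 18.3 and 19.9 by chance, and 0 went opposite ways. KCl and LiCl correlated with r = 0.230 and rho = 0.234 (covariance 0.0439, against r = 0.226 and covariance 0.00697 simulated; 0.198 between other batches), with 61 higher and 63 lower in both, 37.2 and 34.7 by chance, and 29 opposite.

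The hog1 deletion strain, which lacks the osmotic stress kinase, was exposed to KCl to ask which changes need HOG1. RPP0 fell by 1.83 ± 0.16 (SD, n = 2; limma adjusted p = 1.13e-06), NMD2 oligo 3 by 1.28 ± 0.25 and NOP1 by 1.28 ± 0.15, and DTD1 oligo 3 rose by 0.96 ± 0.01 and QCR9 oligo 3 by 1.00 ± 0.00. Splicing factors had 7 of 90 oligos up and 4 down (8 and 4 adjusted over the list alone; camera adjusted p = 0.00893, and 0.304 with an estimated correlation), and ribosomal proteins 8 up and 25 down of 330 (camera adjusted p = 0.980). In all 112 of 1457 oligos changed, 38 upward and 74 downward, and the response correlated with that of the wild type at r = 0.934 and rho = 0.921 across oligos (covariance 0.0948; no shared control, so 0 simulated; r = 0.735 between other batches). The strains shared 38 higher and 73 lower oligos, against 5.63 and 10.6 by chance. Limma called 0 oligos for the difference between the strains. Only 1 had an unadjusted p under 0.05, far fewer than no change would give. With 2 replicates of the deletion this does not show that the responses were equal. GPD1 differed by 0.38 (limma adjusted p = 1.00), by 0.33 within batch A and by 0.52 within batch G, and after 40 min it stood at 0.01 ± 0.22 in the deletion against 0.57 ± 0.34 (n = 4) in the wild type. The deletion's count was 2 without replicate 1 and 12 without replicate 2, and 69 without the 25 oligos that moved together. DTD1 oligo 3, QCR9 oligo 3, NMD2 oligo 3 and NOP1 passed in neither of the first 2 cases.

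Heat shock at 42 degrees Celsius raised chaperone and general stress genes and lowered ribosomal protein genes. HSP104 rose by 3.95 ± 2.17 (SD, n = 2; limma adjusted p = 1.97e-06), the endoplasmic reticulum Hsp70 gene KAR2 by 3.37 ± 2.03 (limma adjusted p = 3.86e-15), SSA4 by 2.92 ± 0.70, SSA2 by 2.80 ± 1.28 and the Hsp40 gene SIS1 by 2.57 ± 1.53. TDH1, a glyceraldehyde-3-phosphate dehydrogenase, rose by 2.79 ± 1.25. The p values here use the spread over all groups of the fit, not that of the 2 heat shock replicates alone. All 8 chaperone oligos and 8 of 10 general stress oligos rose, and 2 of 5 oligos of the unfolded protein response did (3 adjusted over the list alone); camera gave adjusted p = 1.44e-11, 3.79e-07 and 0.00315, and with an estimated correlation adjusted p = 0.0630, 0.130 and 0.0840. Ribosomal protein oligos fell in 148 of 330 cases and rose in 7 (163 and 11 adjusted over the list alone; camera adjusted p = 7.34e-22, and 0.130 with an estimated correlation), with RPS6B oligo 1 at -1.88 ± 0.59 and RPS18B oligo 3 at -1.83 ± 0.66. The other RPS6B oligos lay from -1.18 to -0.13, and RPS18B oligo 1 stood at -0.20. Ribosome biogenesis oligos fell in 16 of 44 cases and rose in 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.00122, and 0.641 with an estimated correlation), with the nucleolar gene NOP56 at -1.96 ± 0.76. The 25 oligos that moved together in KCl were all higher here, with a median of 1.05, among them the Sm protein gene SME1 at 1.21 ± 0.72. They were picked by correlation with NMD2 oligo 3, itself at 1.52 here, so this follows in part from the choice. Limma called 367 of 1457 oligos, 135 upward and 232 downward. With replicate 1 left out the count was 12, and of the genes named here HSP104 (2.41), SSA2 (1.90), TDH1 (1.91), SIS1 (1.48), NOP56 (-1.42), RPS18B oligo 3 (-1.36) and SME1 (0.71) no longer passed.

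After heat shock 194 of 702 oligos differed from their gene's other oligos (limma, 98 upward and 96 downward), in 111 genes. UBC4 oligo 1, for a ubiquitin-conjugating enzyme of the stress response, lay 1.73 ± 0.88 above the gene's others (SD, n = 2; limma adjusted p = 1.83e-09), with its own mean at 1.88 and theirs at 0.15. OM14 oligo 1 and RPL34A oligo 1 lay 1.57 ± 0.99 and 1.42 ± 0.86 above theirs, and RPL7B oligo 3 and RPS0A oligo 2 at -1.44 ± 0.42 and -1.25 ± 0.02. Ribosomal protein genes held a differing oligo in 71 of 98 cases and other genes in 40 of 133 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 8.06e-10). Leaving out replicate 1 reduced the number to 9, with OM14 oligo 1 (0.87), RPL34A oligo 1 (0.82) and RPL7B oligo 3 (-1.14) no longer past the test, and without the noisiest oligos it was 106.

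The herbicide 3-aminotriazole (3-AT, 50 mM) inhibits the histidine enzyme His3, and it was used to ask how cells respond to amino acid starvation. HIS5 and HIS4, genes of histidine synthesis, rose by 2.76 ± 0.48 (SD, n = 3; limma adjusted p = 2.22e-19) and 2.67 ± 0.34 (limma adjusted p = 2.40e-13). MET28 and MET22, of sulfur amino acid metabolism, rose by 1.96 ± 0.39 and 1.76 ± 0.33. The metallothionein gene CUP1-2 rose by 3.49 ± 0.74 (limma adjusted p = 1.44e-11) and the silencing gene SIR1 by 1.65 ± 0.57; the SIR1 spots lie next to those of CUP1-2 in the same array row, and the correlation of the pair over replicate values was 0.762. The Hsp90 gene HSC82 fell by 1.40 ± 0.68, and SSA2 and SSA1 by 1.11 ± 0.68 and 1.03 ± 0.67. Amino acid biosynthesis had 5 of 6 oligos up (5 and 1 adjusted over the list alone; camera adjusted p = 3.08e-11, and 1.97e-05 with an estimated correlation). Chaperones had 3 of 8 oligos down (3 adjusted over the list alone; camera adjusted p = 0.0280, and 0.607 with an estimated correlation) and splicing factors 13 of 90 up (13; 0.0414, and 0.374 with an estimated correlation). Replicate 2 stood apart, with a chaperone median of 0.32 against -0.49 and -1.60 in replicates 1 and 3 and a ribosome biogenesis median of -0.74 against 0.01 and 0.12. Limma called 133 of 1457 oligos, 96 upward and 37 downward, against 32 with these replicates fitted alone. The count was 63 without replicate 1 and 69 without replicate 3. HSC82 (-1.07), SSA2 (-0.79) and SSA1 (-0.67) no longer passed without replicate 3, nor SSA2 without replicate 1 (-1.08).

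Sulfometuron methyl (SMM, 5 ug/mL), which blocks branched-chain amino acid synthesis, raised HIS4 by 1.96 ± 0.12 (SD, n = 2; limma adjusted p = 4.14e-05) and HIS5 by 1.40 ± 0.16. The glycolysis gene PGK1 fell by 1.79 ± 0.04 (limma adjusted p = 1.32e-09), HSC82 by 1.62 ± 0.38 and SSA1 by 1.35 ± 0.22. Amino acid biosynthesis had 3 of 6 oligos up (3 adjusted over the list alone; camera adjusted p = 8.86e-05, and 0.0238 with an estimated correlation) and chaperones 3 of 8 down (3; 0.00241, and 0.485 with an estimated correlation). Limma called 90 oligos, 34 upward and 56 downward; without replicate 1, the replicate hybridised in 1 dye orientation, the count was 8 and HIS5 (1.29), HSC82 (-1.35) and SSA1 (-1.20) no longer passed, and without replicate 2 it was 49. Removal of amino acids from the medium raised MET28 by 4.16 ± 0.65 (SD, n = 2; limma adjusted p = 1.20e-22), HIS4 by 2.10 ± 0.46, MET22 by 1.93 ± 0.17 and HIS5 by 1.48 ± 0.10. The nucleolar gene NOP58 fell by 1.87 ± 0.15, the helicase gene DBP3 by 1.72 ± 0.40 and RPA12, a subunit of RNA polymerase I, by 1.68 ± 0.07. Ribosome biogenesis had 27 of 44 oligos down and 1 up (29 and 1 adjusted over the list alone; camera adjusted p = 2.41e-11), and nitrogen catabolite repression 3 of 4 up (3; 0.0280), each at adjusted p = 0.306 with an estimated correlation. Amino acid depletion changed 331 oligos in limma, 150 upward and 181 downward, against 162 without replicate 1, 117 without replicate 2 and 178 with dye-swapped identifiers only.

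**Figure D1:**
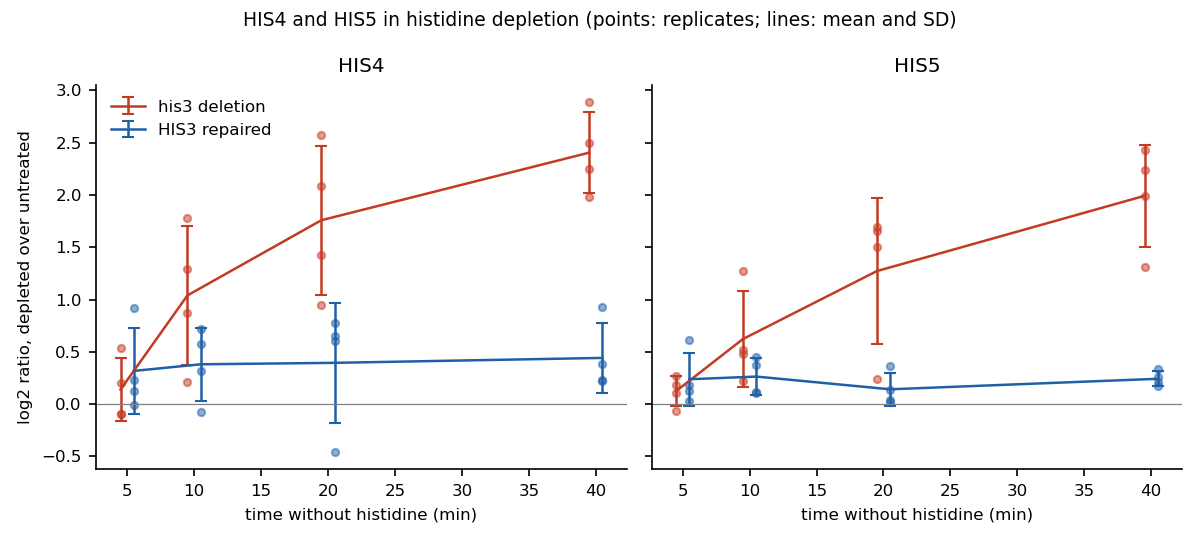
Log2 ratios of HIS4 and HIS5 over time in histidine depletion of the his3 deletion and of the HIS3 repaired strain, with points for replicates and lines through the means. HIS4 stood at 1.76 in the deletion and 0.39 in the repaired strain after 20 min.

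Histidine was removed from cells that lack HIS3 and from cells with HIS3 repaired, to separate starvation from the change of medium. In the deletion HIS4 rose by 1.76 ± 0.71 after 20 min (SD, n = 4; limma adjusted p = 8.82e-08), HIS5 by 1.27 ± 0.69 (1.90e-06) and ADE12, of purine synthesis, by 1.19 ± 0.38. MET22 and the lysine pathway regulator LYS14 rose by 0.61 ± 0.37 and 0.54 ± 0.33, and RPS25B oligo 2, the Ran gene GSP1 and the import receptor gene KAP104 fell by 0.52 ± 0.04, 0.49 ± 0.40 and 0.35 ± 0.22. Amino acid biosynthesis had 3 of 6 oligos up (3 adjusted over the list alone; camera adjusted p = 2.90e-08, and 0.000506 with an estimated correlation). Limma called 10 oligos in the deletion, 7 upward and 3 downward, and 0 in the repaired strain. In the repaired strain 26 of 1457 oligos had an unadjusted p under 0.05, fewer than no change would give. HIS4 and HIS5 stood there at 0.39 ± 0.57 and 0.14 ± 0.16. The strains differed in LYS14, by 0.73 (means 0.54 and -0.19; limma adjusted p = 0.0161; 0.65 in batch A, 0.73 in batch C and 0.82 in batch G), while HIS4 and HIS5 differed by 1.36 and 1.13 and missed the threshold (limma adjusted p = 0.0577). Within batches A, C and G they differed by 1.48, 1.03 and 1.92 for HIS4 and by 1.13, 0.93 and 1.52 for HIS5. For this difference limma called 1 oligo, and 7 (5 upward) with batch as a random block. It also called 7 (5 upward) with the arrays of unsettled direction turned, and again with them left out. Fitted to these groups alone it called 0, both without a batch term and with batch as a fixed term. In the full fit 61 had an unadjusted p under 0.05, which is also fewer than no change would give. Of the amino acid oligos 1 of 6 differed (3 adjusted over the list alone; camera adjusted p = 1.36e-06, and 0.00233 with an estimated correlation). HIS4 stood at 0.14 ± 0.30, 1.04 ± 0.66, 1.76 ± 0.71 and 2.41 ± 0.38 after 5, 10, 20 and 40 min in the deletion, and at 0.44 ± 0.33 after 40 min in the repaired strain. Without replicates 1, 2, 3 and 4 of the deletion its counts were 3, 4, 3 and 19. MET22, LYS14, GSP1 and KAP104 passed only without replicate 4 or with all replicates, RPS25B oligo 2 only with all, and the difference in LYS14 was lost without replicates 1, 2 or 3 of the deletion (0.68 in each case) or replicates 1 or 3 of the repaired strain (0.64 and 0.72).

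Rapamycin (200 ng/mL), an inhibitor of the TORC1 kinase, was compared with cells before treatment, and 1 of its 4 replicates at 20 min ran opposite to the other 3 (correlation across oligos with their mean -0.868). It belongs to 7 array identifiers of batch C whose direction could not be settled, so the values are given as labelled and with these arrays turned. As labelled, limma called 36 oligos, 11 upward and 25 downward; turned, it called 606 (283 and 323), and with these arrays left out 544 (252 and 292, n = 3). DAL80, a repressor of nitrogen genes, stood at 1.08 ± 2.3 as labelled (SD, n = 4; limma adjusted p = 0.0199) and at 2.26 ± 0.18 turned (6.36e-18). The asparaginase gene ASP3-1 stood at 0.63 ± 2.70 as labelled (limma adjusted p = 0.360) and at 2.32 ± 0.80 turned (1.03e-30), and GAC1, of glycogen synthesis, at 0.70 ± 1.72 and 1.63 ± 0.26. RPL34A oligo 3 stood at -1.13 ± 1.88 as labelled (limma adjusted p = 1.79e-06), and turned, RPL28 oligo 2 stood at -1.49 ± 0.18 and the nucleolar gene NOP58 at -1.57 ± 0.35. Ribosomal protein oligos fell in 12 of 330 cases as labelled (27 adjusted over the list alone; camera adjusted p = 3.09e-15, and 0.306 with an estimated correlation) and in 196 turned, where 4 rose (7.69e-33, and 1.95e-05 with an estimated correlation). Ribosome biogenesis oligos fell in 4 of 44 cases as labelled (18 adjusted over the list alone; camera adjusted p = 5.51e-10, and 0.336 with an estimated correlation) and in 34 turned (1.40e-12, and 0.112 with an estimated correlation). Nitrogen catabolite repression had 1 of 4 oligos up as labelled (camera adjusted p = 0.0306, and 0.306 with an estimated correlation) and 3 turned (2.59e-05, and 0.000401 with an estimated correlation). As labelled, the counts without replicates 1, 2, 3 and 4 were 496, 0, 20 and 18, and DAL80 no longer passed without replicates 2, 3 or 4 (0.73, 0.74 and 0.62), nor RPL34A oligo 3 without replicate 2 (-0.22).

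Nitrogen depletion rests on 2 replicates, of which 1 has an unsettled direction, and they correlated at -0.203 across oligos. As labelled, limma called the tubulin oligo TUB3 oligo 3 at -1.12 ± 1.33 and the RNA polymerase II gene RPB7 at -0.64 ± 0.73 (SD, n = 2; limma adjusted p = 0.0481 for both) and 0 oligos upward, with 75 at an unadjusted p under 0.05. Turned, 44 oligos changed, 11 upward and 33 downward, with CUP1-2 at 1.64 and RPL33B oligo 3 at -1.11, and ribosomal proteins had 30 of 330 oligos down (camera adjusted p = 8.23e-15, and 0.00885 with an estimated correlation). With all 7 identifiers of unsettled direction left out, so that the lone replicate was assumed to vary like the other groups, the count was 63. Ribosomal proteins then had 8 oligos up and 18 down (limma's camera, adjusted p = 0.0229, and 0.554 with an estimated correlation). The directions of ribosomal protein and ribosome biogenesis genes were opposite as labelled, upward at camera adjusted p = 8.24e-05 and 2.10e-05 (0.607 and 0.507 with an estimated correlation) with 0 oligos called in limma, against 22 and 4 at an unadjusted p under 0.05. The count was 37 without replicate 1, the one of unsettled direction, alone and 1 without replicate 2, with TUB3 oligo 3 at -0.19 and RPB7 at -0.13.

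Cells deprived of glucose were compared with untreated cells of the same time. The glycogen synthesis regulator GAC1 rose by 3.79 ± 0.57 (SD, n = 2; limma adjusted p = 2.20e-11), HSP104 by 2.64 ± 1.62, the respiratory growth gene ISF1 by 2.55 ± 0.58 (2.08e-19) and TDH1 by 2.53 ± 1.48. The polymerase subunit genes RPC19 and RPA34 fell by 2.10 ± 0.37 and 1.96 ± 0.98, and RPS19B oligo 3 by 1.85 ± 0.50. General stress oligos rose in 5 of 10 cases (6 adjusted over the list alone; camera adjusted p = 0.00109, and 0.374 with an estimated correlation) and glucose derepressed genes in 2 of 3 (2; 0.118). Ribosomal protein oligos fell in 77 of 330 cases and rose in 4 (76 and 4 adjusted over the list alone; camera adjusted p = 1.03e-10, and 0.374 with an estimated correlation), and ribosome biogenesis oligos fell in 19 of 44 (20 adjusted over the list alone, with 1 up; 3.82e-06, and 0.484 with an estimated correlation). Oligos of 1 gene moved apart for 148 of 702 oligos, with MRK1 oligo 2, for a kinase of the glycogen synthase kinase family, at 1.76 ± 0.77 and RPS13 oligo 3 at -1.62 ± 0.46 against their genes' others. Here 40 of 98 ribosomal protein genes and 54 of 133 other genes held such an oligo (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1). Limma called 424 of 1457 oligos, 223 upward and 201 downward, against 181 without replicate 1 (60 for the differences within genes), 231 with dye-swapped identifiers only and 239 without the arrays that lack over 20% of spots. HSP104 (1.49) and TDH1 (1.48) no longer passed without replicate 2.

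Inositol depletion, a condition that activates phospholipid synthesis genes, changed 2 of 1457 oligos at 20 min in limma. At an unadjusted p under 0.05 there were 14, fewer than no change would give. CUP1-2 rose by 3.69 ± 0.38 (SD, n = 2; limma adjusted p = 4.28e-08) and SIR1, whose spots are the neighbours of CUP1-2, by 1.63 ± 0.08 (0.00185), while CUP1-1, chosen after the values were seen, stood at -0.033. The phospholipid list, measured through INO2, OPI1, CPT1 and EPT1, had 0 of 8 oligos past limma's threshold (1 adjusted over the list alone, 1 at an unadjusted p under 0.05), and camera placed it upward against the other oligos (adjusted p = 6.56e-05, and 0.00204 with an estimated correlation). The mating list had 0 of 7 oligos past it in limma (1 at an unadjusted p under 0.05) and a downward camera call (adjusted p = 0.000835, and 0.0236 with an estimated correlation). The count was 1 without replicate 1, and SIR1 no longer passed when either replicate was left out (1.69 without replicate 1 and 1.57 without replicate 2).

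Dithiothreitol (DTT), which disturbs disulfide bonds in the endoplasmic reticulum, was given at 1 mM and 10 mM in 1 replicate of each time, against cells before treatment. The endoplasmic reticulum chaperone gene KAR2 stood at 0.97, 1.98, 3.03 and 2.89 after 5, 10, 20 and 40 min of 1 mM DTT and at 1.47, 1.97, 2.88 and 2.27 in 10 mM, and its partner LHS1 stood at 1.89 after 20 min of 1 mM. HAC1 encodes the transcription factor of the unfolded protein response, and its mRNA loses an intron through Ire1 and tRNA ligase. HAC1 oligo 2 stood at -2.31, -2.39, -2.51 and -0.94 in 1 mM and at -3.42, -2.36, -1.81 and -0.47 in 10 mM after the same times. After 5 min the HAC1 oligos 1 and 3 stood at -0.97 and -1.41 in 1 mM and at -1.15 and -0.91 in 10 mM. With 1 replicate these differences were not tested.

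Some arrays set a deletion strain directly against the wild type. RRP6, which encodes a nuclear exosome exonuclease, stood at -2.10 ± 0.90 in the rrp6 deletion (SD over 13 identifiers) and below 0 on 26 of 26 arrays. In this strain 157 oligos had 1 sign in all 13 identifiers, 66 above and 91 below 0. RPS14B oligo 2 stood at 2.85 ± 0.72, RPS22B oligo 3 at 2.46 ± 0.64, RPL18B oligo 2 at 2.18 ± 0.80 and RPS9A oligo 2 at 2.14 ± 0.66, and TDH1 stood at -2.28 ± 0.59. In the ckb1 ckb2 deletion, which lacks both regulatory subunits of casein kinase 2, 62 oligos had 1 sign in all 13 identifiers, with the tRNA deaminase oligo TAD3 oligo 2 at 0.71 ± 0.26 and the phosphate regulator SPL2 at -1.46 ± 0.97. Genes of mating type also stood far from 0. Of 7 oligos checked for genes expressed in 1 mating type, those of the a type were above and those of the alpha type below 0 in every identifier of both strains. HMRA2, an oligo named for the silent a cassette and not among the 7, stood at -1.41 ± 0.40 in the ckb1 ckb2 deletion. The labels do not state the mating type of the strains, so these strain ratios do not separate the deletion from a difference in mating type. The a-factor genes MFA1 and MFA2 stood at 3.07 ± 0.66 and 3.30 ± 0.73 in the rrp6 deletion and at 3.82 ± 1.19 and 4.98 ± 1.15 in the ckb1 ckb2 deletion. The alpha-factor gene MF(ALPHA)1 stood at -5.42 ± 0.81 and -6.98 ± 1.36 and the a-factor receptor gene STE3 at -2.62 ± 0.73 and -4.42 ± 0.93. The identifiers of a strain cover different treatments and times, so these spreads are not those of replicates and no test was made.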

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

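The limma tests of this part were planned; the counts over other splits of the samples and the tests of explanations were chosen after the result was seen.

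The medians of 14 gene lists were compared between the replicates of each group with 4 replicates, and 4 of 56 had 1 replicate standing apart from the others, where chance gives about 1 in 20 groups, or 2.8. They are the osmotic list in KCl, with replicate 3 at -0.25 and the others from -0.16 to -0.14 (gap over range 0.858), and the glucose derepressed list in the HIS3 repaired strain, with replicate 4 at -0.23 and the others from 0.00 to 0.04 (0.845). The other cases are ribosome biogenesis in the HIS3 repaired strain, with replicate 2 at -0.24 and the others from -0.00 to 0.04 (0.846), and the exosome and RNA decay list in rapamycin, with replicate 1 at 0.23 and the others from -0.19 to -0.14 (0.872). That rapamycin replicate is the 1 of unsettled direction.

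Histidine depletion changed LYS14 differently in 2 strains, by 0.73 between the his3 deletion and the HIS3 repaired strain (limma adjusted p = 0.0161; 4 replicates each). It is the 1 oligo called for that difference, and chance cannot be excluded: of 35 splits of the 8 replicates, the real split called 1 and the highest other called 2, so that 2 splits had a count as large. These splits ignore batch, while LYS14 differed in the same direction within batches A, C and G (0.65, 0.73 and 0.82); batch as a random block gave 7 oligos. A limma fit to these groups alone gave 0 both without a batch term and with batch as a fixed term, against 61 at an unadjusted p under 0.05 in the full fit. For KCl against LiCl the real split called 441 oligos and the highest of the others 278, so that 1 of 35 splits, the real one, had a count as large. That is the lowest share that 35 splits can give, so it argues against a chance split of the replicates but cannot exclude it. These splits ignore batch as well, and the salts share batch H alone (1 KCl and 2 LiCl replicates): in fits to these groups alone limma called 470 without a batch term and 0 with batch as a fixed term, against 588 at an unadjusted p under 0.05 in the full fit.

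Oligos without a gene name were left out of every comparison, and in KCl 37 of these 79 passed limma's threshold (5 higher and 32 lower; 43 at an unadjusted p under 0.05). The number was 24 in LiCl, 29 in glucose depletion, 20 in amino acid depletion and 15 in heat shock. What these oligos read is not stated in the files.

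At 20 min 1 rapamycin replicate ran opposite to the other 3. An exchange of dyes is argued against, since the lowest correlation of the dye effect of these 7 identifiers with that of the others was 0.679, and so is a hybridisation with little signal, since the replicate's correlation with the mean of the others had an absolute value of 0.868. An exchange of treated and control RNA in the labels of the batch C identifiers with the control as channel 1 stays open and may be the source: the other 6 identifiers so labelled also ran against their replicates, with a highest correlation of -0.0867, while 7 of 176 other replicates were negative. No biological explanation was tested.

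In KCl 25 oligos of unrelated genes moved together. A fault of single arrays is argued against, since 17 oligos that follow NMD2 oligo 3 on the 246 identifiers without KCl, NMD2 oligo 3 left out, had a median of -0.58 or lower in each of the 4 replicates (lowest -1.10). A signal shared by these oligos that is not the transcript of the named gene cannot be told apart from a change of those transcripts: the 21 other oligos of the same genes correlated with the cluster's mean at a median of -0.0355, but from -0.65 to 0.78. No biological explanation was tested, and the 25 oligos were lower in KCl and higher in heat shock, with medians of -0.83 and 1.05. As the 25 were picked by their correlation with NMD2 oligo 3 over all replicate values, these medians are not independent of the choice.

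CUP1-2 and SIR1 moved together in inositol depletion and in 3-AT. Signal of a spot reaching the next spot of the same row is a candidate explanation: among the 150 most variable oligos, neighbours in a row had a median correlation 0.153 higher (bootstrap interval 0.101 to 0.197, 279 pairs) than oligos 3 to 5 columns apart, and POP1, the spot beyond SIR1, correlated with CUP1-2 at 0.504. A rise of the transcript of the CUP1 gene copies cannot be told apart from a signal of the CUP1-2 spots alone: CUP1-1 stood at -0.033 in inositol depletion, its correlation with CUP1-2 was 0.0842, and the files do not show whether the CUP1-1 oligo responds to that transcript.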

How the results depend on the processing

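The alternatives with unsettled arrays, gene means, missing spots, both orientations, the oligos that moved together, and batch as a fixed term were chosen after the results were seen, as were the tests of differences within genes; the others were planned. Counts are of oligos past limma's threshold at 20 min, and a count is given here where it moved by more than 1.5 times.

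Subtracting the median of each array, or adding the further heat shock course, moved no count by more than 1.5 times. None of 162 values named in the report reversed its direction under the alternatives run; HAC1 oligo 3 in rapamycin, which the report does not give, went from -0.054 to 0.058 with the unsettled arrays turned. The 162 values were checked 1964 times over alternatives other than leaving out a replicate, and 1864 checks kept their side of the threshold, 78 lost it and 22 gained it; with a replicate left out, 416 of 509 kept it, 87 lost it and 6 gained it.

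With the mean of all oligos of a gene, which tests fewer items, the counts were 237 in KCl (425 as reported), 20 in rapamycin (36), 0 in nitrogen depletion (2), 61 in the hog1 deletion (112) and 5 for the his3 deletion against the HIS3 repaired strain (1). With the noisiest oligos left out, differences within genes numbered 139 in KCl (267), 98 in LiCl (248), 106 in heat shock (194) and 53 in glucose depletion (148), and fewer oligos of each gene are left by construction; nitrogen depletion had 0 and inositol depletion 1 (2). Fits to the compared replicates alone have fewer replicates to estimate the spread, and gave 269 in LiCl (493), 0 differences within genes in LiCl, 32 in 3-AT (133), 3 in the his3 deletion (10), 0 in rapamycin and 0 for the his3 deletion against the repaired strain. Identifiers with both orientations alone gave 8 in SMM (90), 178 in amino acid depletion (331), 18 in the his3 deletion, 81 in rapamycin, 1 in nitrogen depletion, and 231 oligos (424) with 75 differences within genes in glucose depletion; fewer replicates remain, and the cause was not tested further. Arrays with the treated RNA in Cy5 alone gave 82 in the his3 deletion, 271 in rapamycin, 0 in nitrogen depletion, 56 in inositol depletion and 2 for the his3 deletion against the repaired strain; the dye effect does not cancel there by construction.

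Turning the unsettled arrays gave 606 in rapamycin, 44 in nitrogen depletion, 20 in the his3 deletion and 7 for the difference between the his3 strains, and leaving them out gave 544, 63, 19 and 7. Leaving out arrays with over 20% of spots missing gave 0 in rapamycin, 0 in nitrogen depletion, 239 in glucose depletion with 74 differences within genes, and 4 for the his3 strains. The median of the copies gave 0 in nitrogen depletion and 2 for the his3 strains, the dye effect subtracted 3 for the his3 strains, and batch as a random block (correlation 0.195) 1 in nitrogen depletion and 7 for the his3 strains. Without the oligos that moved together the hog1 deletion had 69; 21 of them are among its calls, and the rest of the change was not tested. Batch as a fixed term, with the compared groups alone, gave 0 for the his3 strains and 0 for KCl against LiCl. These groups alone without a batch term gave 0 and 470, so the batch term changed the count in the second case only, where the salts share 1 batch alone; the cause was not tested. For the counts of 0 in this part, limma's counts as reported at an unadjusted p under 0.05 were 251 in rapamycin, 75 in nitrogen depletion, 61 for the his3 strains, 588 for KCl against LiCl and 292 for the differences within genes in LiCl. The 75 and 61 are near or below what no change would give. List tests called numbered 60 with the preset correlation and 6 with an estimated correlation. For other alternatives in this paragraph the cause was not tested.

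Leaving out each replicate in turn gave ranges of 259 to 387 in KCl, 352 to 424 in LiCl, 19 to 58 in NaCl, 12 to 267 in heat shock, 63 to 116 in 3-AT, 8 to 49 in SMM, 117 to 162 in amino acid depletion, 3 to 19 in the his3 deletion, 0 to 0 in the HIS3 repaired strain, 0 to 7 for the difference between these strains, 2 to 12 in the hog1 deletion, 0 for its difference from the wild type, 335 to 418 for KCl against LiCl, 181 to 304 in glucose depletion, 1 to 2 in inositol depletion, 1 to 37 in nitrogen depletion and 0 to 496 in rapamycin. For differences within genes they were 168 to 231 in KCl, 125 to 217 in LiCl, 9 to 161 in heat shock and 60 to 101 in glucose depletion. The lowest came without replicate 2 in KCl, 2 in LiCl (3 for differences within genes), 1 in NaCl, 1 in heat shock, 1 in 3-AT (69 without 3), 1 in SMM, 2 in amino acid depletion, 1 or 3 in the his3 deletion, 1 in the hog1 deletion, 1 in glucose depletion, 1 in inositol depletion, 2 in nitrogen depletion and 2 in rapamycin. The HIS3 repaired strain and the difference of the hog1 deletion from the wild type, with 0 called, had 26 and 1 at an unadjusted p under 0.05 in limma with all replicates. Both are fewer than no change would give. Where 1 replicate remained, it was assumed to vary like the other groups.

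No paired analysis was possible because the labels do not say that equal replicate numbers of different groups share a culture; the batches that replicates share were used instead, as a random block and as a fixed term, with the counts given above. A comparison of intron with junction oligos was not run, since the kind of an oligo cannot be read from the files. Signal over background is not in the files, so how far weak spots limit the results was not examined.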

Other observations

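The test of the rrp6 oligos in this part, and the choice of those oligos, were made after the results were seen; the list tests and the similarity of responses were planned.

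Some list results are not in the report. Exosome and RNA decay genes had 4 of 25 oligos up and 1 down in KCl (limma's camera, adjusted p = 0.928) and 1 up and 8 down in LiCl (2 and 8 adjusted over the list alone; camera adjusted p = 0.185 from limma), and meiosis genes had 4 of 35 up and 1 down in LiCl (3 and 0 adjusted over the list alone; camera adjusted p = 0.402 from limma). In rapamycin as labelled, exosome genes had 2 of 25 oligos down (limma's camera, adjusted p = 0.00349, and 0.247 with an estimated correlation; turned, 4 up and 13 down, 0.0526) and meiosis genes 3 of 35 up (limma's camera, adjusted p = 0.0134, and 0.406 with an estimated correlation; turned, 7 up and 1 down, 0.103). The mating list had 4 of 7 oligos down in heat shock (limma's camera, adjusted p = 0.208). Of the phosphate list, which was too small to test, the oligo of the regulator SPL2 stood at 0.58 in KCl and -1.30 in LiCl, and that of the activator PHO4 at -0.30 and -0.34. SPL2 was missing in the 2 LiCl replicates of batch H, so its LiCl value does not rest on them.

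Heat shock and glucose depletion correlated at r = 0.669 and rho = 0.755 across 1457 oligos (covariance 0.189, against r = 0.251 and covariance 0.0104 simulated with a shared control and no effect; r = 0.608 between replicates of other batches). They shared 54 higher and 94 lower oligos, against 20.7 and 32.0 by chance, and 1 went opposite ways.

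Groups with 1 replicate at 20 min gave the following log2 ratios, without a test. In sorbitol ALD3 stood at 1.47, TDH1 at 1.19 and DBP2 oligo 3 at -1.14. In phosphate depletion SPL2 stood at 2.22, HIS4 at 1.35 and the nuclear RNA binding protein gene HRP1 at -1.47. TBB left HSP104 at 2.12, SIS1 at 1.56, DBP2 oligo 3 at -1.87 and RRS1 at -1.68. With 3-AT and rapamycin together CUP1-2 stood at 2.70, HIS5 at 2.07 and ASP3-1 at 2.00. In KCl, RPP0 stood at -1.32 in the edc2 deletion, -1.82 in the ckb1 ckb2 deletion and -1.92 in the rrp6 deletion, and SUP16 stood at 1.71 in the edc2 deletion. The ckb1 ckb2 deletion in 3-AT had CUP1-2 at 3.18, HIS5 at 2.00 and HIS4 at 1.92, and the cka2 deletion in SMM had HIS4 at 2.25 and TDH1 at -3.01. In single arrays of deletion strains over the wild type, MFA2 stood at 5.86 and MF(ALPHA)1 at -9.60 in the ckb1 deletion, and at 3.76 and -5.93 in the ckb2 deletion.

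Combined treatments and wortmannin, with 2 replicates each, were not tested either. KCl with TBB left SUP16 at 1.69 ± 0.14 (SD, n = 2) and RPP0 at -1.97 ± 0.27. TBB added to 3-AT, over 3-AT alone, left SSA4 at 3.95 ± 0.59, HSP104 at 2.80 ± 1.53 and SSA2 at 2.17 ± 0.02, with a chaperone list median of 1.84 ± 0.35. The same treatment over cells before treatment, in 1 replicate at 20 min, had HSP104 at -1.48, HSC82 at -1.79 and a chaperone list median of -0.43, while at 15 min, in 2 replicates, that median was 0.67 ± 0.50 and SSA4 stood at 2.27 ± 1.16. Wortmannin left GAC1 at 2.42 ± 0.93, HSP104 at 1.91 ± 0.58 and RPS13 oligo 3 at -1.52 ± 0.09. KCl with 3-AT left HSP104 at 2.00 ± 0.73 and SSA4 at 1.65 ± 0.03, and nitrogen depletion with 3-AT left HSP104 at -2.16 ± 0.31.

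In the rrp6 deletion over the wild type 22 of 702 oligos lay above their gene's other oligos in all 13 identifiers, and by more than 0.5 on average. Of these, 11 were for ribosomal proteins. In the ckb1 ckb2 deletion 2 of the 702 oligos met both limits, and they are not among the 22. The highest of the 22 there was IMD4 oligo 1 at 0.37. The median difference within genes of the 22 rrp6 oligos was set against 10000 random draws of oligos of the same genes. It was -0.37 in LiCl (percentile 0.03), -0.24 in KCl (0.32), -0.15 in NaCl (0.86), -0.16 in glucose depletion (2.2), -0.12 in KCl in the hog1 deletion (1.21) and 0.099 in SMM (97.4). The percentile was 37.8 in 3-AT, 9.21 in amino acid depletion, 32.05 in the his3 deletion, 84.4 in the HIS3 repaired strain and 46.7 in inositol depletion. Rapamycin and nitrogen depletion are left out here, since their direction is not settled. Part of the low values in KCl and LiCl may follow from the choice of the oligos: some of the 13 identifiers set the deletion over the wild type in the same treatment, which favours oligos that are low in the treated wild type. A hypothesis is that these oligos read unspliced RNA that may also be more abundant after heat shock; it cannot be told apart from no change, since the median there was -0.042 (bootstrap interval -0.18 to 0.15, percentile 42.3). The files do not say which part of a gene an oligo reads, so the RNA forms stay unknown.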
